A study of Homo sapiens with 12 samples.

How the data were processed

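Poly(A) RNA from HCT116 TIM-mAID cells was sequenced, a human colorectal carcinoma line in which TIMELESS carries an auxin-inducible degron tag. The 12 libraries fall into 4 groups of 3, all taken at 40 h: DMSO, 5-Ph-IAA at 1 µM, the ATR inhibitor ceralasertib at 1 µM (ATRi), and 5-Ph-IAA with ATRi (5-Ph-IAA/ATRi). Group and set number were taken from the sample titles, and per the series' design text the 3 libraries of a group are biological replicates. Per the labels' protocols, RNA was isolated with a column kit and a DNase step, and libraries were made with a directional kit.

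The deposited table holds estimated counts for 62700 genes in 12 columns, made by the authors with Salmon, per the submitters' processing notes. Those notes list FastQC 0.12.1, Trim Galore 0.6.7, cutadapt 3.4, STAR 2.7.9a, SAMtools 1.17 and Salmon 1.10.1 with genome build GRCh38.p14. The annotation release, the strand setting of the counting and any read filter are not given in the sources used here. Of the deposited estimated counts, 13.6% were not whole numbers and 6.93% lay more than 0.01 from a whole number. Values rounded to whole numbers were used for all tests. Because estimated counts divide reads among similar transcripts, genes with near-identical copies are reported as uncertain. Antisense and overlapping genes carry the same uncertainty, since the strand setting is not known. Gene positions are those of the RefSeq annotation of GRCh38.p14, matched by symbol for 222 of 231 named genes. Gene lengths, meaning the genomic span, come from a GENCODE annotation instead. Transcript length and GC content are those of the longest transcript of a gene in that same annotation.

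Counts were normalised by TMM and filtered with filterByExpr (minimum count 10, minimum total count 15), which kept 18049 genes holding at least 99.89% of the counts of each library. Differences were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in a single model of all 12 libraries with 1 mean per group. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The contrasts were 5 pairwise comparisons and the interaction, which asks whether the log2 change in the combination differs from the sum of both single changes. Fold changes are given as log2 values ± standard error, and levels as TMM-scaled CPM ± SD with n = 3. The median biological coefficient of variation was 0.214. Counting floors cover counting error only. Pairs of replicates differed by far more than sampling noise, with a chi-square of 17.3 to 255.6 per gene, so no library was a second copy of another.

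The 23 gene lists, their members, the design, the tests and the rule for named genes were fixed before the data were examined. Named genes are 12 fixed genes, the 6 largest rises and 6 largest falls per pairwise comparison (5 and 5 for the interaction), and up to 4 members of each list with the smallest adjusted p. A largest rise or fall had to pass the threshold, reach a mean of 5 CPM in the higher group, carry a gene symbol and, in a pairwise comparison, separate all libraries of both groups. Values of some named genes are not reported here. Lists were tested with camera (preset inter-gene correlation 0.01, lists of at least 3 tested members), with Benjamini-Hochberg adjustment over 138 tests. Each list was tested again with the correlation estimated from the data and with fry. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Single values per library were compared by 2-sided exact permutation tests, which cannot go below p = 0.1 for 3 against 3.

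The procedure was tested on simulated data drawn from the real means, dispersions and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. For the combination against DMSO, edgeR recovered 47% of the 2-fold and 73% of the 4-fold changes among 17460 genes, with 9 false calls. For 5-Ph-IAA against DMSO the shares were 40% and 73%, with 4 false calls, and for ATRi against DMSO 47% and 75%, with 3. For the interaction they were 15% and 59%, with 3 false calls. DESeq2 recovered 62% and 82% for the combination against DMSO, with 41 false calls. The simulation holds no variation shared between genes within a group, which the real libraries do show. Camera called a list shifted 1.5-fold and 0 of 100 unshifted lists.

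Alternatives fixed in advance were DESeq2 size factors, total counts, upper quartile factors, no and stricter count filters (at least 1 CPM in 3 libraries and 50 counts in total), unrounded counts, a 2-fold minimum, DESeq2 1.42.0, limma-voom, a fit of only the compared groups, the set number as a block, and leaving out each library in turn. A covariate for the share of mitochondrial counts, a covariate for the first within-group component, a fit of 8 libraries without the highest mitochondrial share of each group, lists without shared members, and list tests with an estimated correlation without each library were added after seeing the data. The fit of 8 libraries leaves out DMSO 2, 5-Ph-IAA 1, ATRi 1 and 5-Ph-IAA/ATRi 1, so DMSO keeps other set numbers than the other groups. It leaves shares of 6.63% and 7.85% with DMSO and of 10.7% and 12.0% with the combination. That fit therefore does not balance the share between groups. The within-group component comes from the same libraries, so its covariate lowers the within-group spread by construction. Nothing in the table was left out beyond the count filter.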

Results

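Steady-state poly(A) RNA was measured in HCT116 TIM-mAID cells after 40 h with DMSO, with 5-Ph-IAA, with ATRi or with both compounds, in 3 libraries per group. 5-Ph-IAA is an auxin analogue that brings degron-tagged proteins to a ubiquitin ligase, here TIMELESS, a component of the replication fork protection complex. ATRi is ceralasertib, an inhibitor of the ATR kinase, which signals stalled replication forks. The series title places the experiment in a study of DNA-PKcs, JNK and p53 in the choice between cell fates during replication catastrophe. The comparisons ask what each compound does alone, what the combination does, and whether the combination departs from the sum of its parts.

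Library totals, in mega counts (M), ranged from 27.7 M to 34.7 M. The group means were 31.8 M ± 2.21 with DMSO, 31.2 M ± 3.12 with 5-Ph-IAA, 34.0 M ± 1.15 with ATRi and 28.3 M ± 0.188 with the combination (SD, n = 3). The difference of means was -3.50 M between the combination and DMSO and -5.73 M between the combination and ATRi (2-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 allows). Transcripts of the mitochondrial genome took 6.63% to 14.9% of the counts. Their mean share was 9.81% with DMSO, 10.1% with 5-Ph-IAA, 10.6% with ATRi and 12.2% with the combination, and the difference of 2.40 percentage points between the combination and DMSO did not pass (2-sided exact permutation p = 0.5, n = 3 per group). Libraries within a group differed along 1 shared component that held 56.1% of the within-group variance. Its score rose with the mitochondrial share: across the 12 libraries Pearson's r within groups was 0.959 and Spearman's rho 0.965 (exact permutation p = 0.000772 for each), and r was 0.942 without the 2 libraries farthest from the median share. The nuclear RNA MALAT1, the stress gene DDIT3 and CHAC1 were high in libraries with high scores, while the chaperone gene HSPA8 and the replication helicase genes MCM2 and MCM4 were high in those with low scores. So were DLGAP5, INCENP, ECT2, ANLN and SHCBP1, genes of mitosis and cytokinesis. MALAT1 ranged from 1122 CPM in DMSO 3 to 10180 CPM in DMSO 2.

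**Figure D1:**
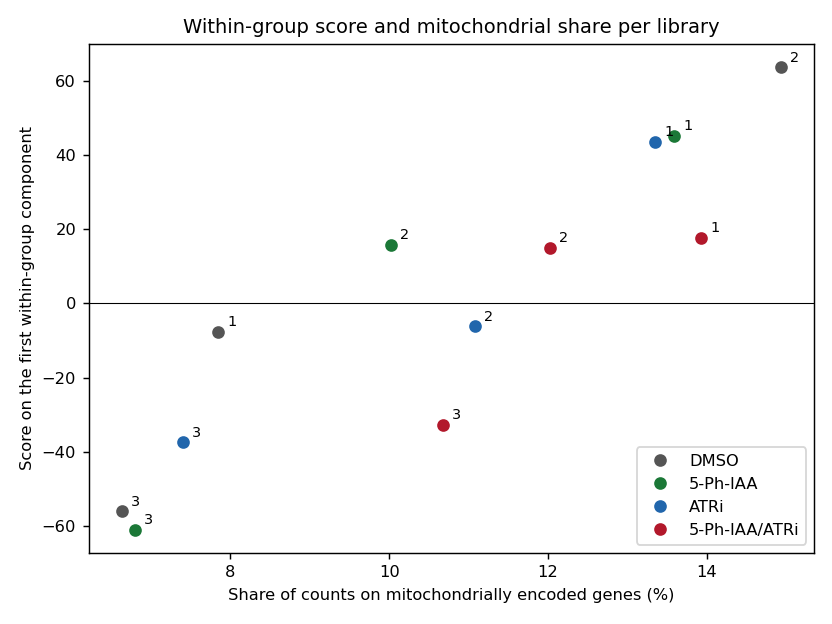
Score of each library on the first within-group component (vertical axis, no unit) against its share of counts on mitochondrially encoded genes (horizontal axis, percent); each point is 1 library, coloured by group and numbered by set. The 4 libraries with the highest shares, from 13.4% to 14.9%, all score above 0, and the 3 libraries with the lowest shares and set number 3 score -37.5 or lower.

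TIMELESS (ENSG00000111602.12; GRCh38.p14 chromosome 12, 56416363 to 56449426) is targeted as a protein, so its RNA does not check the labels. Its level was 50.2 CPM ± 18.7 with DMSO, 48.0 ± 13.02 with 5-Ph-IAA, 36.5 ± 9.05 with ATRi and 22.2 ± 3.97 with the combination (SD, n = 3). Against DMSO the log2 fold change was -0.07 ± 0.29 with 5-Ph-IAA and -0.46 ± 0.29 with ATRi, neither past the threshold, and TIMELESS RNA fell with the combination (-1.18 ± 0.30, edgeR adjusted p = 0.0233). That call was lost without DMSO 1, DMSO 3 or any combination library, with log2 fold changes between -1.44 and -0.90 in the 6 refits. Its log2 fold change in the combination was -1.11 ± 0.30 against 5-Ph-IAA (adjusted p = 0.0377, lost without any library but 5-Ph-IAA 1) and -0.72 ± 0.29 against ATRi (adjusted p = 0.239), and its interaction value was -0.65 ± 0.41 (adjusted p = 0.887). The transcripts of its partner TIPIN (-0.23 ± 0.22), of ATR (-0.13 ± 0.11) and of PRKDC, which encodes DNA-PKcs (-0.50 ± 0.44), did not pass the test in the combination. The log2 fold change of CHEK1 was -1.25 ± 0.39 (adjusted p = 0.0581), which passed without DMSO 2.

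With 5-Ph-IAA alone, genes activated by p53 were higher as a group, by small amounts, and 1 gene passed the threshold. SULF2 (chromosome 20), which encodes an extracellular sulfatase acting on heparan sulfate, rose from 11.6 CPM ± 0.688 to 22.1 ± 0.931 (log2 fold change 0.93 ± 0.10, edgeR adjusted p = 0.0341). Of 44 tested p53 target genes, 41 had a positive log2 fold change, with a median of 0.35. None of the 44 passed over all genes and 12 were higher adjusted over the list alone (7 without DMSO 3 or 5-Ph-IAA 3). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, went from 217.6 CPM ± 25.2 to 435.3 ± 81.8 (log2 fold change 1.00 ± 0.18, adjusted p = 0.532). FDXR, the mitochondrial ferredoxin reductase, had 0.71 ± 0.12 (adjusted p = 0.408), and MDM2, the ligase that degrades p53, 0.37 ± 0.21 (adjusted p = 1). The p53 list as a whole rose by camera (adjusted p = 8.75e-48; adjusted p = 0.000401 with an estimated correlation).

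The list of pro-apoptotic genes and death receptors had a median of 0.09 (0.15 without DMSO 3; camera adjusted p = 0.000508; adjusted p = 0.0357 with an estimated correlation). With an estimated correlation that call was lost without any 1 of the 6 libraries (adjusted p between 0.0527 and 0.181) and with 8 libraries (adjusted p = 0.132), and without the members shared with the p53 list the camera adjusted p was 0.105. Another 6 lists passed camera with 5-Ph-IAA alone, and none of them with an estimated correlation. Integrated stress response genes had a median of -0.33 (camera adjusted p = 8.53e-12; adjusted p = 0.297 with an estimated correlation). It was -0.05, -0.11, -0.17, -0.56 and -1.0 without DMSO 2, 5-Ph-IAA 3, 5-Ph-IAA 1, DMSO 3 and 5-Ph-IAA 2. The camera call of that list was lost without DMSO 2 or 5-Ph-IAA 3 and with 8 libraries, where the median was 0.06 (adjusted p = 0.913). Homologous recombination and Fanconi genes, unfolded protein response genes, sterol synthesis genes, hypoxia and glycolysis genes and markers of other cell types had adjusted p values of 0.699, 0.331, 0.553, 0.528 and 0.0531 with an estimated correlation, in that order. Their camera calls were lost without DMSO 1, DMSO 3, 5-Ph-IAA 1 or 5-Ph-IAA 2 for recombination genes, without DMSO 3 or 5-Ph-IAA 1 for unfolded protein response genes and without DMSO 2 or 5-Ph-IAA 3 for sterol and hypoxia genes. With the mitochondrial covariate those of recombination and unfolded protein response genes were lost, and with 8 libraries those of unfolded protein response, sterol and hypoxia genes. The cell type markers passed with an estimated correlation without DMSO 2 (adjusted p = 0.0461) and with the axis covariate (adjusted p = 0.0243). G2/M and mitotic genes had a median of -0.02 (-0.27 and -0.34 without DMSO 2 and 5-Ph-IAA 3, and 0.26 and 0.14 without DMSO 3 and 5-Ph-IAA 2, each past camera; 0.09 with the mitochondrial covariate, camera adjusted p = 0.0247, and -0.16 with 8 libraries, camera adjusted p = 0.000509). Aryl hydrocarbon receptor targets, a check on an indole compound, had a median of -0.03 (0.18 without DMSO 3 and -0.13 without 5-Ph-IAA 3), with CYP1A1 at 0.50 ± 0.24 (adjusted p = 1). G2/M genes, these targets, AP-1 genes and interferon response genes had medians below 0 and upward tests, none past camera. At an unadjusted p under 0.05 edgeR gave 239 genes, and 3.37% of genes had all 3 libraries of a group above all 3 of the other, where chance gives 10%. The SULF2 call was lost without any 1 of the 6 libraries and with limma-voom, where 0 genes passed. DESeq2 gave 15 genes, the axis covariate 14 and the mitochondrial covariate 8.

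With ATRi alone, 12 genes rose and none fell in the main fit, and 6 of the 12 are members of the p53 target list (2, 3 and 3 list members passed without DMSO 1, DMSO 3 and ATRi 2). The largest rises were CDKN1A (757.2 CPM ± 140; log2 fold change 1.80 ± 0.18, edgeR adjusted p = 0.00407), TP53INP1 (1.45 ± 0.20, adjusted p = 0.0265), the stress-inducible sestrin gene SESN1 (1.29 ± 0.14), SULF2 (1.28 ± 0.10, adjusted p = 0.00125), FDXR (1.21 ± 0.12) and PHLDA3, a repressor of AKT signalling (1.08 ± 0.12). The p53 list rose with a median of 0.71 (camera adjusted p = 6.6e-87; adjusted p = 0.000168 with an estimated correlation), and 30 of its 44 tested members were higher adjusted over the list alone. MDM2 had a log2 fold change of 1.13 ± 0.21 (adjusted p = 0.123). Pro-apoptotic genes and death receptors rose as a list (median 0.17; adjusted p = 0.0102 with an estimated correlation, 0.0707 with 8 libraries), with BAX at 0.81 ± 0.16 and the death receptor FAS at 1.09 ± 0.23, neither past the threshold. Without the members shared with the p53 list, the camera adjusted p was 0.0106.

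All 36 G2/M and mitotic genes were negative with ATRi alone, with a median of -0.65 (-0.38 without DMSO 3; camera adjusted p = 1.28e-26; adjusted p = 0.169 with an estimated correlation). Integrated stress response genes (median -0.76), G1/S and DNA replication genes (-0.50), homologous recombination and Fanconi genes (-0.56), fork protection and ATR-CHK1 signalling (-0.33), end joining genes (-0.09) and replication-dependent histone genes (0.37) also passed camera. With an estimated correlation their adjusted p values were 0.215, 0.498, 0.252, 0.354, 0.18 and 0.108, the last 0.0477 without DMSO 2. Without DMSO 3 the medians of G1/S, recombination, fork protection, end joining and histone genes were -0.14, -0.26, -0.11, -0.03 and 0.22, with the G1/S, fork protection and end joining calls lost. Without DMSO 2 those of stress response and G1/S genes were -0.35 and -0.82. The fork protection median was also -0.21, -0.19 and -0.18 without DMSO 1, ATRi 1 and ATRi 2. The end joining call was also lost without these 3 libraries, and its median was -0.15 without ATRi 3. In the same way AP-1 and immediate early genes, NF-kB and inflammatory secretory genes, interferon response genes, sterol synthesis genes, ribosome biogenesis genes, hypoxia and glycolysis genes and markers of other cell types passed only with the preset correlation. Their adjusted p values were 0.552, 0.584, 0.699, 0.552, 0.331, 0.352 and 0.311 with an estimated correlation. The camera calls were lost without DMSO 1, DMSO 3, ATRi 1 or ATRi 2 for AP-1 genes and cell type markers and DMSO 1, DMSO 3, ATRi 2 or ATRi 3 for NF-kB genes. They were lost without DMSO 1, DMSO 3 or ATRi 2 for interferon genes, DMSO 2 or ATRi 3 for sterol genes and DMSO 2 for ribosome biogenesis and hypoxia genes. The mitochondrial covariate ended those of AP-1, NF-kB, interferon and end joining genes and cell type markers, the axis covariate those of AP-1, NF-kB and interferon genes, and the fit of 8 libraries those of sterol, ribosome biogenesis and hypoxia genes. The NF-kB list had a negative median beside a mean of 0.10 and an upward test, and the JNK and p38 and unfolded protein response lists, not past camera, had a mean below 0 and an upward test. Of all genes 8.80% separated the libraries of both groups, and 877 had an unadjusted p under 0.05. The TP53INP1 call was lost without any library but DMSO 2, the SESN1 call without DMSO 1 or ATRi 2, and the PHLDA3 call without DMSO 1 or DMSO 3. The count of 12 fell to 3, 4, 6, 4 and 7 without DMSO 1, DMSO 3, ATRi 1, ATRi 2 and ATRi 3, to 1 with 8 libraries and to 0 when only these groups were fitted. It was 28 (24 higher, 4 lower) without a count filter, 19 (17 higher, 2 lower) with upper quartile factors and 95 (66 higher, 29 lower) with DESeq2. DESeq2 made more false calls than edgeR in simulation, where it was run only for comparisons that include the combination. With the axis covariate the count was 218 (125 higher, 93 lower) and with the mitochondrial covariate 143 (87 higher, 56 lower), and 1 of the 6 genes without ATRi 1 fell. The set number as a block also raised the count, with genes both higher and lower, as given in the section on processing.

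The combination changed far more genes. Against DMSO 1126 genes rose and 1244 fell of 18049 tested, 1103 of them by at least 2-fold. p53 targets rose and every tested member of the G2/M and mitotic list fell. CDKN1A (ENSG00000124762.14; chromosome 6, 36676463 to 36687332) reached 2062 CPM ± 44.5 from 217.6 ± 25.2 (log2 fold change 3.24 ± 0.19, edgeR adjusted p = 6.23e-06). MDM2 (ENSG00000135679.27; chromosome 12, 68808172 to 68850686) reached 561.2 CPM ± 65.7 from 135.8 ± 23.1 (2.05 ± 0.22, adjusted p = 0.000213). TP53I3, which encodes an oxidoreductase (chromosome 2, 24077433 to 24084834), reached 212.7 CPM ± 29.8 from 19.2 ± 5.59 (3.47 ± 0.23, adjusted p = 1.24e-05). FDXR (chromosome 17, 74862497 to 74872994) rose by 2.51 ± 0.12 and PHLDA3 by 2.0 ± 0.12. Of the 44 tested p53 targets 37 rose, none fell and 7 did not pass, with a median of 1.48, and 38 were higher adjusted over the list alone (camera adjusted p = 1.04e-72; adjusted p = 0.000212 with an estimated correlation).

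**Figure D2:**
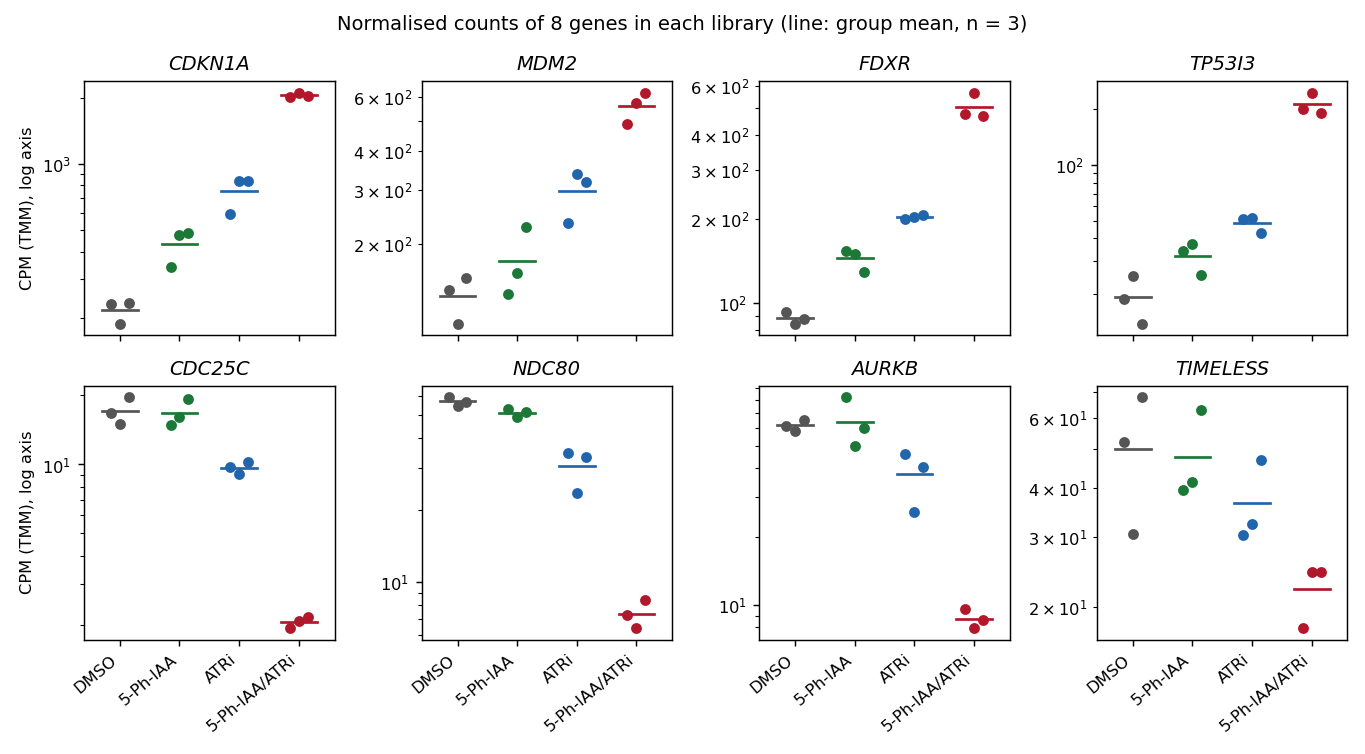
CPM after TMM scaling (vertical log axis) of 4 p53 target genes (CDKN1A, MDM2, FDXR and TP53I3), 3 mitotic genes (CDC25C, NDC80 and AURKB) and TIMELESS in each library, by group; points are libraries and lines are means of n = 3. The mean of CDKN1A goes from 217.6 with DMSO to 2062 with the combination, and that of CDC25C from 17.1 to 2.06.

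Of 27 tested pro-apoptotic genes and death receptors 7 rose (3 without DMSO 1 or combination 3) and none fell, among them FAS (2.26 ± 0.24), BAX (1.40 ± 0.16) and the nuclease gene AEN (1.61 ± 0.25), all of which are also p53 list members. The list had a median of 0.39 (adjusted p = 0.0119 with an estimated correlation, 0.0707 with 8 libraries), and without shared members its camera adjusted p was 0.0164. BBC3, which encodes PUMA, had a log2 fold change of 0.62 ± 0.30 (adjusted p = 0.206). Anti-apoptotic genes went both ways, as the mitotic survivin gene BIRC5 fell (-2.0 ± 0.34) while BAG3 (1.05 ± 0.18), BAG1 (0.66 ± 0.14) and CFLAR (0.60 ± 0.12) rose, and the list did not pass camera (adjusted p = 0.135). Of 24 AP-1 and immediate early genes 4 rose (2 without combination 1, 8 without DMSO 2), among them FOSB (2.15 ± 0.22) and IER5 (0.95 ± 0.15; list median 0.57, camera adjusted p = 0.00024; adjusted p = 0.331 with an estimated correlation). JUN had 0.80 ± 0.30 (adjusted p = 0.112) and ATF3 1.33 ± 0.56 (adjusted p = 0.153), and these and BBC3 passed without DMSO 2. In the JNK and p38 cascade 2 genes rose (1 without DMSO 1, DMSO 3 or any combination library), among them MAP2K3 (0.72 ± 0.12). Another 2 fell (1 without DMSO 1 or any combination library, 4 without DMSO 2), among them MAP3K5 (-0.80 ± 0.14), and 23 of 27 did not pass (median 0.02, mean -0.03, downward test with camera adjusted p = 0.881).

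Genes of cell division fell together. All 36 G2/M and mitotic genes fell, with a median of -2.21 (camera adjusted p = 5.9e-63; adjusted p = 0.0462 with an estimated correlation). With an estimated correlation that call was lost without DMSO 1, DMSO 3 or any combination library (adjusted p between 0.0616 and 0.076), with the mitochondrial covariate (adjusted p = 0.0607) and with 8 libraries (adjusted p = 0.163). The list member DLGAP5 was also high in libraries with low scores on the within-group component. CDC25C (ENSG00000158402.21; chromosome 5, 138285265 to 138338355), the phosphatase that activates CDK1, went from 17.1 CPM ± 2.37 to 2.06 ± 0.117 (log2 fold change -3.06 ± 0.16, edgeR adjusted p = 2.65e-06). The kinetochore genes NDC80 (-2.94 ± 0.16) and SPC25 (-3.25 ± 0.41), the kinesin gene KIF15 (-2.98 ± 0.26), the centromeric histone gene CENPA (-2.51 ± 0.17) and the kinase gene AURKB (-2.82 ± 0.24) fell. The DNA helicase gene PIF1 (-3.28 ± 0.30) and the DNA glycosylase gene NEIL3 (-2.97 ± 0.34) were also among the largest falls. Of 48 G1/S and DNA replication genes 26 fell and none rose, among them TK1 (-1.87 ± 0.32) and CDC45 (-2.28 ± 0.42), with a median of -1.37 (camera adjusted p = 1.3e-14; adjusted p = 0.358 with an estimated correlation). Its members MCM2 and MCM4 were also high in the libraries with low scores on the within-group component. Without DMSO 1, DMSO 3, combination 1, combination 2 and combination 3 the number of list members that fell was 11, 11, 11, 9 and 13. Without DMSO 3 a single member rose and the median was -0.99. Without DMSO 2 the number was 39, with a median of -1.75, and with 8 libraries 24, with a median of -1.68.

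Genes of fork and DNA repair pathways fell in part. Of 33 homologous recombination and Fanconi genes 21 fell (10 without DMSO 1, DMSO 3, combination 1 or combination 2, 11 without combination 3), among them RAD51AP1 (-2.32 ± 0.36), EME1 (-2.26 ± 0.35) and FANCI (-2.07 ± 0.34). That list had a median of -1.19 (adjusted p = 0.215 with an estimated correlation). Of 25 genes of fork protection and ATR-CHK1 signalling 7 fell (3 without DMSO 1, combination 1 or combination 3, 4 without DMSO 3 or combination 2, 12 without DMSO 2), including RHNO1, a partner of the checkpoint clamp (-1.39 ± 0.12), and ZRANB3, a fork remodelling enzyme (-1.62 ± 0.23; list median -0.64, and -0.35 without DMSO 3; adjusted p = 0.331 with an estimated correlation). Of 23 end joining genes 3 fell, among them POLQ (-2.53 ± 0.32) and XRCC1 (-0.68 ± 0.14), and 20 did not pass (median -0.30; adjusted p = 0.0612 with an estimated correlation, 0.0475 without DMSO 2). POLQ acts in polymerase theta-mediated joining and XRCC1 in single-strand break repair. Replication-dependent histone genes went the other way: 10 of 30 tested rose (6 without DMSO 1, DMSO 3 or combination 1) and none fell, with a median of 1.18, and examples H2BC21 (2.04 ± 0.20) and H2BC12 (1.37 ± 0.15). Their camera adjusted p was 2.03e-09, and adjusted p = 0.0736 with an estimated correlation (0.0477 without DMSO 2). These RNAs largely lack poly(A) tails and their copies are near-identical, so their counts are uncertain; H4C12 had no count in any DMSO library, and the median was the same with it at its bound.

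Of 37 interferon response genes 18 rose (8 without DMSO 1 or combination 2, 9 without DMSO 3) and none fell, with 24 higher adjusted over the list alone and a median of 0.70 (camera adjusted p = 1.41e-11; adjusted p = 0.215 with an estimated correlation). OASL (2.37 ± 0.29), OAS1 (2.07 ± 0.35) and IFIT3 (1.82 ± 0.30) were among them, and 17 of 36 rose when the p53 list member TRIM22 was left out. Of 29 NF-kB and inflammatory secretory genes 6 rose (3 without combination 1 or combination 2) and 1 fell (0 without any 1 of the 6 libraries), with a median of 0.50 (0.27 without DMSO 3; adjusted p = 0.354 with an estimated correlation). The collagenase gene MMP1 rose by 4.47 ± 0.50 from 0.0834 CPM to 1.94 CPM, the cytokine gene CSF1 by 0.81 ± 0.15 and RELB by 0.82 ± 0.17. Largest rises outside these lists were PURPL, a p53-responsive long noncoding RNA (4.03 ± 0.31), the sortilin-family receptor gene SORCS2 (3.84 ± 0.35) and the orphan nuclear receptor gene NR4A3 (3.67 ± 0.32), from DMSO means of 1.19, 0.441 and 0.477 CPM. A gene row named 7SK (1 of 7 rows of that name) had 0 counts in all DMSO and 5-Ph-IAA libraries, 189, 0 and 104 with ATRi and 305, 415 and 107 with the combination. Against a floor of 3 counts over the DMSO group, it was at least 309.8-fold higher in the combination. This small nuclear RNA is not polyadenylated and has many copies, so the assignment is uncertain, and the call was lost without DMSO 1, combination 1 or combination 2.

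Metabolic and differentiation lists were mixed. Integrated stress response genes fell in 11 of 26 cases (7 without DMSO 1 or combination 1, 6 without combination 2) and rose in none, with a median of -1.10 (-0.70 without DMSO 2; camera adjusted p = 1.2e-09; adjusted p = 0.331 with an estimated correlation). The members that fell include the serine synthesis genes PHGDH (-2.65 ± 0.30) and PSAT1 (-2.07 ± 0.39), the mitochondrial folate enzyme gene MTHFD2 (-1.14 ± 0.21) and the cystine transporter gene SLC7A11 (-2.48 ± 0.46). With 8 libraries 4 of the 26 fell, with a median of -0.68. The list members DDIT3 and CHAC1 were also high in libraries with high scores on the within-group component. The sterol synthesis gene SREBF1 fell (-0.88 ± 0.17), with the list not past camera (median -0.16, adjusted p = 0.333; -0.43 and 0.00286 without DMSO 2, 0.09 and 0.69 without DMSO 3). Hypoxia and glycolysis genes split into 2 that rose (1 or 0 without any library but DMSO 2) and 4 that fell (2 without DMSO 1, combination 1 or combination 3), including PDK1 (-0.99 ± 0.16; list median -0.07, camera adjusted p = 0.324; -0.23 and 0.0214 without DMSO 2, 0.05 and 0.82 without DMSO 3). NRF2 targets split likewise, as AKR1B10 (3.35 ± 0.39) and HMOX1 (1.08 ± 0.13) rose and 3 members fell, among them SLC7A11 and NQO1 (-0.56 ± 0.12; list median -0.02, upward test with camera adjusted p = 0.714). Of 9 aryl hydrocarbon receptor targets ALDH1A3 rose (1.60 ± 0.18) and NQO1 fell (list median 0.26, camera adjusted p = 0.152). Unfolded protein response genes did not pass (0 of 20, median -0.10, camera adjusted p = 0.742), and their median was 0.02 without DMSO 3. Ribosome biogenesis genes rose in 4 of 30 cases (1 without DMSO 1, combination 1 or combination 2, 2 without DMSO 3, 0 without combination 3), with a median of 0.26 (0.14 without combination 3; camera adjusted p = 0.00234; adjusted p = 0.354 with an estimated correlation).

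Of 12 intestinal epithelial differentiation genes 3 rose and 1 fell (1 and 0 without DMSO 1, DMSO 3 or any combination library), led by the cell adhesion gene CEACAM1 (3.88 ± 0.23, from 0.661 CPM to 9.82 CPM), with a median of 0.36 (0.18 and 0.22 without DMSO 2 and combination 2; adjusted p = 0.126 with an estimated correlation). The mitochondrial covariate ended the camera calls of that list and of cell type markers. Of 24 markers of other cell types 10 were measured, and ACTA2 (1.91 ± 0.21), CD68 (1.94 ± 0.30) and CD14 (2.42 ± 0.37) rose (list median 0.32, and 0.58 without DMSO 2; adjusted p = 0.169 with an estimated correlation). ACTA2 encodes a smooth muscle actin, CD68 a lysosomal protein and CD14 a monocyte receptor, and their combination means were 27.9, 33.6 and 0.634 CPM. All 13 mitochondrially encoded genes had positive values with a median of 0.44, none past the threshold (camera adjusted p = 0.053), beside a mitochondrial share of 12.2% against 9.81%. Their median was 0.83 without DMSO 2, 0.26 without DMSO 1 and 0.17 without DMSO 3, the last 2 with 11 of 13 positive (camera adjusted p = 0.000181, 0.147 and 0.335), and the list passed without combination 2 or combination 3 (0.0407 and 0.0376). Of all genes 32.3% separated the libraries of both groups. The count of 2370 was 1236, 1348, 1363 and 1305 without DMSO 1, combination 1, combination 2 and combination 3, 6552 with the axis covariate and 6873 with the mitochondrial covariate.

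**Figure D3:**
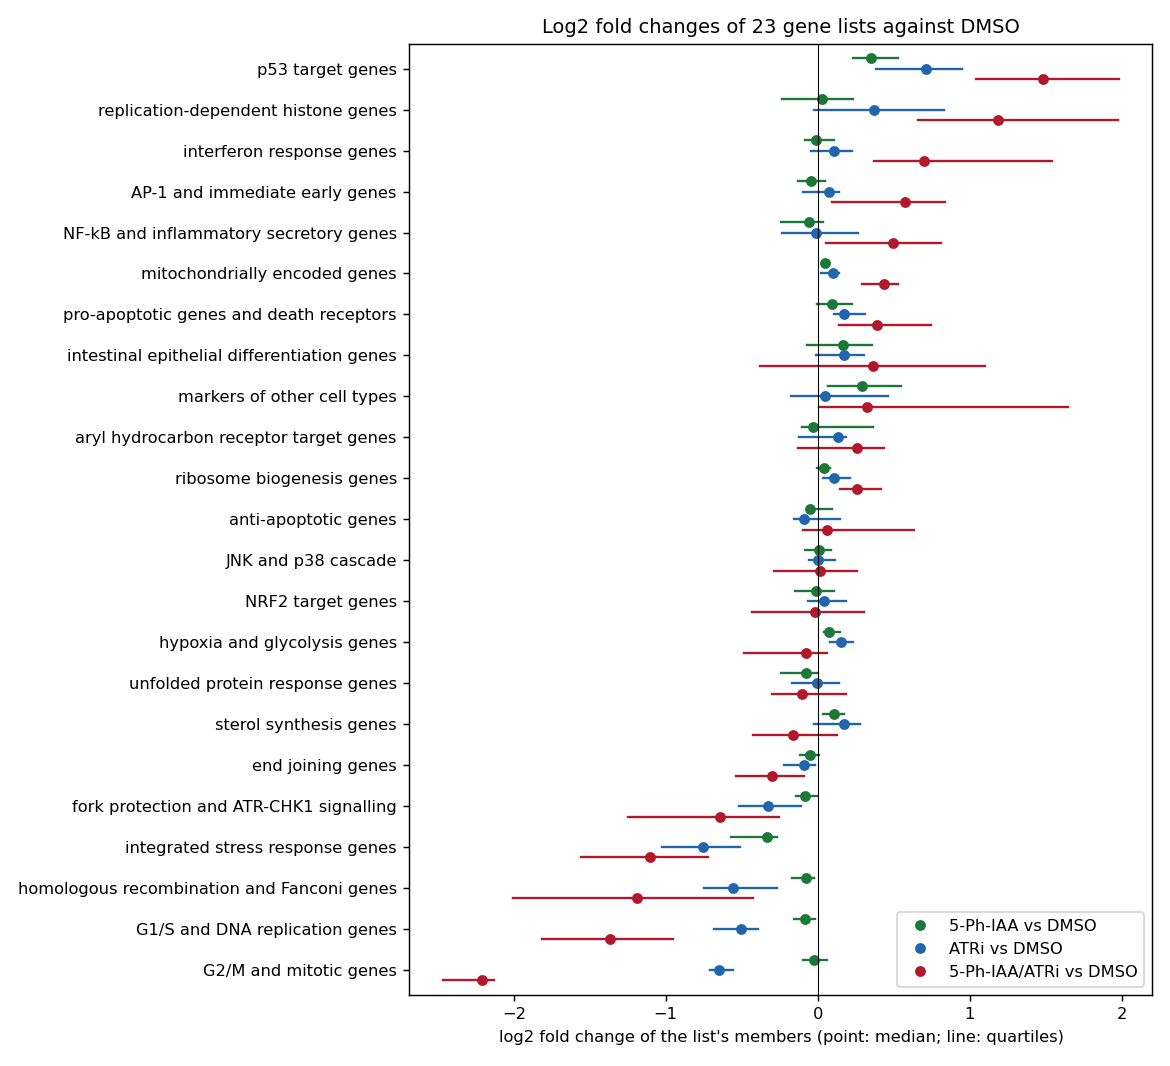
Log2 fold change against DMSO of the tested members of 23 gene lists (horizontal axis) with 5-Ph-IAA, ATRi or both, lists ordered by their median in the combination; points are medians and lines run from the lower to the upper quartile of the members. The p53 list lies at 0.35, 0.71 and 1.48, and the G2/M list at -0.02, -0.65 and -2.21.

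Adding ATRi to 5-Ph-IAA raised 790 genes and lowered 909. p53 targets rose and mitotic genes fell, as against DMSO: 31 of 44 p53 targets rose (median 1.1; adjusted p = 0.000401 with an estimated correlation) and 35 of 36 G2/M genes fell (median -2.20; adjusted p = 0.0356 with an estimated correlation, and between 0.0527 and 0.0668 without 5-Ph-IAA 1, 5-Ph-IAA 3, combination 1 or combination 2 and 0.154 with 8 libraries). CDKN1A rose by 2.24 ± 0.19 (edgeR adjusted p = 6.77e-05), TP53I3 by 2.72 ± 0.23, CEACAM1 by 2.89 ± 0.22 and CCN2, a matricellular growth factor gene, by 2.61 ± 0.35. PIF1 (-3.21 ± 0.30), CDC25C (-3.02 ± 0.16), AURKB (-2.88 ± 0.24) and the centromere gene CENPI (-2.86 ± 0.44) fell. Of 27 pro-apoptotic genes and death receptors 7 rose, including the TRAIL receptor gene TNFRSF10A (0.98 ± 0.23). The list's adjusted p was 0.0266 with an estimated correlation, a call lost without 5-Ph-IAA 1, 5-Ph-IAA 3 or combination 2 and with 8 libraries. The number of its genes that rose was 2, 3, 4, 4 and 2 without 5-Ph-IAA 1, 5-Ph-IAA 2, combination 1, combination 2 and combination 3. Interferon response genes rose in 17 of 37 cases (10, 11, 5 and 11 without 5-Ph-IAA 1, 5-Ph-IAA 2, combination 2 and combination 3). Histone genes rose in 9 of 30 and NF-kB genes in 6 of 29 (2 without 5-Ph-IAA 1, combination 1 or combination 2, 3 without combination 3). The 3 lists had adjusted p = 0.187, 0.0557 (0.0486 without combination 1) and 0.29 with an estimated correlation. The TNFRSF10A call was lost without 5-Ph-IAA 1, 5-Ph-IAA 2, combination 1 or combination 3. The carbonic anhydrase gene CA9, induced by hypoxia, fell by 2.27 on the log2 scale ± 0.44. Of the 1699 genes, 1556 were also called in the same direction against DMSO, a comparison that shares the combination libraries. The count was 1122, 819, 826 and 777 without 5-Ph-IAA 2, combination 1, combination 2 and combination 3, and 805 with 8 libraries and 1033 when only these groups were fitted. It was 5575 with the axis and 5876 with the mitochondrial covariate.

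Adding 5-Ph-IAA to ATRi raised 294 genes and lowered 340. CDKN1A rose by a further 1.45 ± 0.18 (edgeR adjusted p = 0.00262), TP53I3 by 2.13 ± 0.22, FDXR by 1.31 ± 0.12 and PHLDA3 by 0.92 ± 0.12. All 44 tested p53 targets were positive, 23 rose (6, 9 and 7 without ATRi 1, 2 and 3, and 8, 6 and 5 without combination 1, 2 and 3) and 33 were higher adjusted over the list alone (median 0.79; camera adjusted p = 3.25e-39; adjusted p = 0.000667 with an estimated correlation). CEACAM1 (2.56 ± 0.22), NR4A3 (2.45 ± 0.30) and the matricellular genes CCN1 (2.16 ± 0.22) and CCN2 (2.17 ± 0.34) were among the largest rises, while KRTAP2-3 (2.24 ± 0.46), of a family of near-identical copies, is uncertain and was lost without any library but ATRi 1. Of 36 G2/M genes 22 fell (14, 12, 11, 11 and 12 without ATRi 1, ATRi 3, combination 1, combination 2 and combination 3) and all 36 were lower adjusted over the list alone (median -1.63; adjusted p = 0.0443 with an estimated correlation, between 0.0556 and 0.076 without these 5 libraries and 0.186 with 8 libraries). They were led by CDC25C (-2.24 ± 0.16), AURKB (-2.11 ± 0.23), NDC80 (-2.04 ± 0.16) and CENPA (-1.84 ± 0.17). PIF1 (-2.64 ± 0.30) and RHNO1 (-0.92 ± 0.11) fell.

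Of 37 interferon response genes 8 rose (5 without combination 1, 1 without ATRi 1, ATRi 3, combination 2 or combination 3), with OASL at 1.96 ± 0.29 (list median 0.74, and 0.43 without combination 2; adjusted p = 0.169 with an estimated correlation). Pro-apoptotic genes and death receptors had 1 rise, FAS (1.16 ± 0.23), and a median of 0.20 (adjusted p = 0.043 with an estimated correlation, lost without ATRi 1, ATRi 3, combination 2 or combination 3 and with 8 libraries), and the camera adjusted p without members shared with the p53 list was 0.0931. Histone genes (2 of 30 rose, 1 without any 1 of the 6 libraries, with H2BC21 at 1.21 ± 0.19), AP-1 genes (1 of 24, FOSB at 1.51 ± 0.22) and NF-kB genes (0 of 29, median 0.31) had adjusted p = 0.126, 0.311 and 0.354 with an estimated correlation. Of all genes 26.9% separated the libraries of both groups. The count of 634 fell to 179, 220 and 200 without ATRi 1, ATRi 2 and ATRi 3, and to 163, 162 and 134 without combination 1, 2 and 3. With 8 libraries it was 64, with only these groups fitted 970, with DESeq2 1348, with the axis covariate 3718 and with the mitochondrial covariate 3474. The FAS call was lost without any 1 of the 6 libraries.

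In the test of the interaction, 12 genes were lower and 2 higher in the combination than the sum of both single changes gives. Of the 12 lower genes 4 are on the G2/M and mitotic list: CDC25C (-2.20 ± 0.21, edgeR adjusted p = 0.00358), AURKB (-2.16 ± 0.32, adjusted p = 0.0394), NDC80 (-1.88 ± 0.22) and CENPA (-1.80 ± 0.23). The kinetochore gene NUF2 (-2.02 ± 0.30) is another of the 12. PIF1 (-2.57 ± 0.39) and SAMD11 (-1.95 ± 0.27) were also lower, and CCN1 (2.13 ± 0.30) and the nuclear receptor gene NR4A1 (1.53 ± 0.18) higher. CCN1 had means of 12.6, 12.8, 16.8 and 74.8 CPM with DMSO, 5-Ph-IAA, ATRi and both. All 36 G2/M genes had negative interaction values, and 32 passed adjusted over the list alone (20 or 21 without 5-Ph-IAA 3, ATRi 3, combination 1 or combination 2), with a median of -1.61 (camera adjusted p = 4.56e-73; adjusted p = 0.0357 with an estimated correlation). Over all genes 4 of them passed, 1 without DMSO 1, ATRi 3, combination 1 or combination 2 and 2 without 5-Ph-IAA 1, 5-Ph-IAA 3, ATRi 1 or combination 3. The p53 list was higher than the sum (median 0.43, camera adjusted p = 9.53e-12; adjusted p = 0.0266 with an estimated correlation), with no member past the threshold, TP53I3 at 1.38 ± 0.30 (adjusted p = 0.201) and CDKN1A at 0.45 ± 0.25 (adjusted p = 0.829). With an estimated correlation the G2/M call was lost in 9 of the 12 refits without 1 library, all but those without 5-Ph-IAA 2, ATRi 2 or combination 3 (adjusted p up to 0.0747), and with 8 libraries (adjusted p = 0.192). The p53 call was lost in the 7 without DMSO 1, DMSO 3, 5-Ph-IAA 1, ATRi 1, ATRi 3, combination 2 or combination 3 (adjusted p up to 0.074).

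Interferon response genes had a median interaction of 0.79 (camera adjusted p = 3.65e-16; adjusted p = 0.162 with an estimated correlation), with OASL at 1.60 ± 0.40. Another 10 lists passed camera with the preset correlation and none of them with an estimated one, among them G1/S genes (-0.78), sterol synthesis genes (-0.43) and histone genes (0.90), at adjusted p = 0.402, 0.354 and 0.138 with an estimated correlation. The G1/S median was -0.42, -0.51, -0.43 and -1.23 without 5-Ph-IAA 3, ATRi 3, DMSO 2 and DMSO 3. The sterol median was -0.27 and -0.23 without 5-Ph-IAA 3 and DMSO 2, and the histone median 0.38 without DMSO 2. Of the genes named here CDC25C passed in each of the 12 refits without 1 library, and the others lost the call without DMSO 1, ATRi 3, combination 1 or combination 2, and all but NDC80 also without further libraries. At an unadjusted p under 0.05 there were 1317 genes. Leaving out 1 library gave 2 to 15 genes, and the count was 2 without DMSO 1, ATRi 3, combination 1 or combination 2, 4 without 5-Ph-IAA 3, ATRi 1 or combination 3, and 5, 7 and 9 without 5-Ph-IAA 1, DMSO 3 and DMSO 2. With 8 libraries 0 genes passed, limma-voom gave 9 and DESeq2 186. Without a filter 47 genes passed (4 higher, 43 lower), with the mitochondrial covariate 304 (91 higher, 213 lower) and with the axis covariate 620 (216 higher, 404 lower). The set number as a block also raised the count, as given in the section on processing.

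The single compounds shared 1 call, SULF2, where lists of 1 and 12 genes drawn independently from 18049 share 0.000665 genes. Across genes, which are not independent replicates, the log2 fold changes of both compounds against DMSO correlated with r = 0.507. Simulated groups with no change, set against the same DMSO libraries, gave a mean r of 0.507 (0.471 to 0.537 in 20 simulations) and 0 shared calls. The covariance was 0.0654, against 0.0674 to 0.0826 in the simulations and 0.0964 from the variance of the DMSO libraries. Shared controls alone can therefore give as much. Simulated genes varied independently, unlike those of the real libraries, so these values do not decide whether the compounds share a response. All 12 genes called with ATRi alone were also called in the same direction in the combination against DMSO, a comparison that uses the same controls.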

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

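The interaction test and the tests of length and GC content, library thinning and the linear scale were fixed before their results were seen. The bounds for the mitochondrial share as a cause of the gene group changes were also set before that test's result. The mitochondrial covariate itself was added after seeing the data, so that check was not planned from the start. The tests of the axis against the mitochondrial share and the set number, of single libraries behind the p53 rise and of aryl hydrocarbon receptor targets were chosen after. The genes and lists of the interaction stand here by 1 rule: the effect of 5-Ph-IAA differed between cells with and without ATRi by the interaction test. The p53 rise with 5-Ph-IAA alone, the axis within groups and the splits of the pairwise comparisons were not chosen by that rule.

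That test passed for 14 genes, and for more with the set number as a block, as given in the section on processing. The log2 interaction was -2.57 for PIF1, -2.20 for CDC25C, -2.16 for AURKB, -2.02 for NUF2, -1.95 for SAMD11, -1.93 for FAM72D, -1.88 for NDC80, -1.86 for HJURP, -1.80 for CENPA, -1.51 for CDKN3, -1.36 for CPS1 and -1.36 for PCDH7. It was 2.13 for CCN1 and 1.53 for NR4A1. FAM72D has near-identical copies, so its value is uncertain. Of 100 splits of the 12 libraries into 4 groups of 3, the real one included, 5 gave at least 14 genes, and the highest other count was 3203. The splits mixed libraries of all 4 groups, without regard to the set number or the within-group axis. Changes in the treated groups therefore enter their interaction contrast. Such splits are no sample of groups without an interaction, so they cannot decide whether chance gave the count, and chance is not excluded. Splits that called several times the real count point to a structure of the samples, which may be the treatments themselves.

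Among lists, the mean log2 interaction was -1.62 for G2/M and mitotic genes, -0.74 for G1/S and DNA replication genes, -0.61 for homologous recombination and Fanconi genes, -0.43 for sterol synthesis genes, -0.38 for hypoxia and glycolysis genes, -0.34 for fork protection and ATR-CHK1 signalling and -0.20 for end joining genes. It was 0.78 for interferon response genes, 0.60 for histone genes, 0.51 for NF-kB genes, 0.45 for AP-1 genes, 0.43 for p53 targets and 0.12 for anti-apoptotic genes. With an estimated correlation the p53 and G2/M lists passed, though in 7 and 9 of the 12 refits without 1 library they did not, nor did the G2/M list with 8 libraries (adjusted p = 0.192), and the other 11 lists did not pass. Single libraries moved several means. Without DMSO 2 they were -0.41 for G1/S, -0.40 for recombination, -0.24 for sterol, -0.17 for fork protection, 0.34 for histone, 0.21 for NF-kB, 0.27 for AP-1 and 0.19 for anti-apoptotic genes. Without 5-Ph-IAA 3 they were -0.36 for G1/S, -0.38 for recombination, -0.25 for sterol, -0.14 for fork protection, -0.13 for end joining, 0.29 for AP-1 and 0.24 for anti-apoptotic genes. Without DMSO 3 they were -1.16 for G1/S, -0.54 for fork protection, -0.67 for sterol and 0.02 for anti-apoptotic genes, and without ATRi 3 -0.49 for G1/S, -0.22 for fork protection and 0.21 for anti-apoptotic genes. Histone genes had 1.15 without 5-Ph-IAA 2 and 0.33 without DMSO 1, NF-kB genes 0.79 without 5-Ph-IAA 2 and interferon genes 0.50 without combination 2. The histone means include H4C12, which had no count in any DMSO library. With H4C12 at its bound the histone mean against DMSO went from 0.19 to 0.090 with 5-Ph-IAA and from 0.59 to 0.49 with ATRi. In the combination it went from 1.38 to 1.28. The interaction mean with that bound was not computed. Anti-apoptotic genes had 0.013, 0.049 and 0.053 without 5-Ph-IAA 1, ATRi 1 and combination 3. The calls were lost without DMSO 2 or 5-Ph-IAA 3 for fork protection, without DMSO 2, 5-Ph-IAA 3, ATRi 3 or combination 2 for end joining and without DMSO 3, 5-Ph-IAA 1, ATRi 1 or combination 3 for anti-apoptotic genes. Of the 100 splits 37 gave at least 13 lists, with 18 in the highest other. For the reason given above they cannot decide whether chance gave the number of lists, and chance is not excluded.

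G2/M genes fell further in the combination than both single changes add up to. With the mitochondrial share as a covariate 92.5% of the list's median was kept (-1.61 became -1.49). The range was 87.4% to 95.9% over resampled list members, which leaves out the spread between libraries. The kept median argues, for this list only, against RNA quality as the whole cause, as far as the mitochondrial share shows it. Of all lists and comparisons that covariate ended 18 calls, among them the interactions of anti-apoptotic and end joining genes. With all libraries thinned to the smallest total 100.3% was kept, and 13 genes passed in the interaction. The fall was the same at equal totals, and the median absolute change of a member was 0.0095 on the log2 scale. Thinning was bound to keep the median nearly as it was, so this result does not decide on library size. Thinning leaves the expected level of a gene as it was, so it cannot test a difference that arose before counting. The totals of the combination lay below those of DMSO and ATRi in every library, so what else goes with the totals stays open. On the linear scale 100% of the members, 36 of 36, fell by more than the sum, against 47.8% of all genes, which argues against the log scale. A departure from additivity of both compounds on mitotic transcripts stays open beside it.

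p53 targets were higher with 5-Ph-IAA alone. The list's median kept 107% with the mitochondrial share as a covariate (0.35 became 0.37). The range was 93.8% to 124.9% over resampled list members, which leaves out the spread between libraries. The mean shares were close, 9.81% with DMSO and 10.1% with 5-Ph-IAA, so the covariate could move this list little. The kept median is therefore only weak evidence against RNA quality, as far as the mitochondrial share shows it. Its mean kept at least 85.8% without any 1 library (0.38 with all, 0.33 to 0.44 without 1), which argues against a single library as the cause. An action of 5-Ph-IAA apart from the tagged protein stays open. Aryl hydrocarbon receptor targets had a median of -0.033 (0.18 without DMSO 3 and -0.13 without 5-Ph-IAA 3). Other actions were not measured and cells without the tag were not analysed here. Loss of TIMELESS is the other open explanation, and the design gives no value that separates them.

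Libraries of a group differed along 1 shared axis, for which no biological explanation was tested. Its score followed the log2 mitochondrial share (r = 0.959), so RNA quality may account for it. Set number took 72.2% of the variance of the score (exact permutation p = 0.0370), so a batch shared by libraries of 1 number stays open too. Correction for transcript length and GC content left 92.7% of the score's SD, which argues against these as the whole cause.

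For the pairwise comparisons there are 10 splits of 6 libraries, too few for a share under 0.05. For 5-Ph-IAA against DMSO the real split gave 1 gene and the highest other 4213, so 2 of 10 gave as many. That other split set DMSO 1, DMSO 3 and 5-Ph-IAA 3 against the rest, the lower against the higher mitochondrial shares, and points to a structure of the samples. For ATRi, the combination against DMSO and the combination against 5-Ph-IAA, the real split gave 12, 2370 and 1699 genes and the highest other 0, and for the combination against ATRi 634 and 1. For lists, adjusted within 1 comparison, the real splits gave 6, 16, 16, 15 and 19 and the highest others 13, 14, 15, 15 and 16, in the same order with 5-Ph-IAA first, so that 9, 1, 1, 2 and 1 of 10 splits gave as many.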

How the results depend on the processing

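The covariates for the mitochondrial share and the within-group axis, the fit of 8 libraries and the lists without shared members were chosen after seeing the data. The fit of 8 libraries leaves no overlap of mitochondrial shares between DMSO and the combination and unlike set numbers, so changes under it may come from either. No named gene reversed under any alternative run. With 1 library left out named gene results kept their side of the threshold 1527 times, 429 calls were lost and 6 were gained, and the cause was not tested beyond the smaller number of samples. At the real depth and spread 47% of simulated 2-fold changes were recovered for the combination against DMSO, and the simulation did not vary depth. DESeq2 made 41 false calls in that simulation, against 9 by edgeR. The median biological coefficient of variation was 0.115 with the axis and 0.129 with the mitochondrial covariate, against 0.214. The axis is computed from the within-group variation of these same libraries, so its covariate lowers the spread by construction. Higher counts with it are therefore no separate support. How far the lower spread raised the counts was not tested.

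For 5-Ph-IAA against DMSO, 0 genes passed with a 2-fold minimum, total counts, upper quartile factors, no count filter, 8 libraries, only the compared groups or limma-voom, 14 with the axis covariate, 8 with the mitochondrial covariate and 15 with DESeq2, against 1. For ATRi against DMSO (12), upper quartile factors gave 19 (17 higher, 2 lower), no filter 28 (24 higher, 4 lower), the axis 218 (125 higher, 93 lower), the mitochondrial share 143 (87 higher, 56 lower), DESeq2 95 (66 higher, 29 lower), 8 libraries 1 and only the compared groups 0. The combination against DMSO (2370) gave 1103 with a 2-fold minimum, 6552 with the axis and 6873 with the mitochondrial share. The combination against 5-Ph-IAA (1699) gave 798, 5575 and 5876 in the same order, 805 with 8 libraries and 1033 with only the compared groups. The combination against ATRi (634) gave 306, 3718 and 3474 in that order, 64 with 8 libraries, 970 with only the compared groups and 1348 with DESeq2. The interaction (14) gave 47 without a filter, 620 with the axis, 304 with the mitochondrial share, 0 with 8 libraries, 186 with DESeq2 and 9 with limma-voom.

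Leaving out 1 library gave 0 to 0 genes for 5-Ph-IAA against DMSO, 3 to 11 for ATRi, 1236 to 2376, 777 to 1334 and 134 to 220 for the combination against DMSO, 5-Ph-IAA and ATRi, and 2 to 15 for the interaction. The cause was not tested.

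With the set number as a block the counts were 1, 100 (55 higher, 45 lower), 4569, 3546, 1980 and 215 (45 higher, 170 lower) for the interaction, and the overlap of the single compounds stayed at 1; 2 list calls were lost and 2 gained. The labels do not say that a number marks a shared batch, and 13 of 18 same-numbered pairs correlated over 0.1 (lowest r = -0.094, highest 0.756), so the numbers were not taken to pair the libraries. As a hint from the data, 8 of 12 libraries correlated best with their own number.

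Lists whose test turned direction, with a call before or after, had these means. For 5-Ph-IAA against DMSO with 8 libraries, G2/M genes had -0.16, NF-kB genes 0.27 and sterol genes -0.029. For the same comparison, leaving out 1 library gave -0.21 to 0.16 for AP-1, -0.47 to 0.33 for G1/S, -0.31 to 0.25 for G2/M, -0.35 to 0.14 for recombination, -0.036 to 0.19 for hypoxia, -0.26 to 0.50 for mitochondrially encoded and -0.089 to 0.33 for sterol genes. For ATRi against DMSO the ranges were -0.041 to 0.19 for interferon genes and -0.050 to 0.37 for sterol genes, and for the interaction -0.56 to 0.53 for stress response genes. These turns arose without DMSO 2, DMSO 3, ATRi 2 or a 5-Ph-IAA library, and the cause was not tested. Further means changed sign without meeting that rule. Among them, with 5-Ph-IAA, were NF-kB genes (0.19 without DMSO 2, 0.010 without 5-Ph-IAA 3), stress response genes (0.086 without DMSO 2) and mitochondrially encoded genes (-0.086 without DMSO 1), and stress response genes in the interaction (0.011 without DMSO 1). With an estimated correlation 71 list calls were lost, with fry 52 (1 gained), with the mitochondrial covariate 18 (4 gained), with the axis covariate 6 (5 gained) and with 8 libraries 11 (14 gained, 3 turned).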

Other observations

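The test of gene length was chosen before its result was seen. Whether long genes fell more than short genes in the combination against DMSO was asked as a hypothesis. Across 17277 genes with a length, which are not independent replicates, Spearman's rho of log2 fold change and gene length (genomic span) was -0.133, and -0.134 without the cell cycle and p53 lists. In 4 classes of equal size, from the shortest to the longest genes, the median log2 fold change was 0.05, 0.02, -0.02 and -0.13. Among the shortest genes 321 genes rose and 132 fell, and among the longest 170 rose and 485 fell. With 5-Ph-IAA alone rho was -0.094 and with ATRi alone -0.079. The bounds set in advance were -0.2 for a trend and -0.1 for none. A trend also needed a slope on log10 length lower in every combination library than in every DMSO library, and it was not: combination 3 had 1.29, against 1.28 and 1.11 in DMSO 1 and DMSO 2. That comparison crosses set numbers. Within a number the combination had the lower slope each time (1.12 against 1.28, 1.07 against 1.11 and 1.29 against 1.43), though the numbers were not taken to pair the libraries. Slopes also differed within groups along with the mitochondrial share. DMSO 2, 5-Ph-IAA 1 and ATRi 1, with shares of 13.4% to 14.9%, had slopes of 1.06 to 1.11. DMSO 3, 5-Ph-IAA 3 and ATRi 3, with 6.63% to 7.40%, had 1.34 to 1.47. The mean share was 12.2% with the combination and 9.81% with DMSO, so its lower slopes were not separated from that axis. The values do not meet the bounds for a trend, and rho lies between them, so the question stays open.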
